A study of Mus musculus with 12 samples.

How the data were processed

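RNA sequencing of mouse kidney was analysed from 1 table that covers 12 libraries in 4 groups of 3. The groups are wild type (WT) and Lrrk2 knockout, each after sham surgery or after ischemia and reperfusion (I/R). Per the labels, I/R was ischemia of the left kidney for 30 min at 37 °C together with removal of the other kidney, and sham animals had the same surgery without the ischemia. The reperfusion time, sex and age of the animals are not given in the sources used here. The groups labelled knockout are written KO sham and KO I/R, and these names carry the label only. Per the labels' protocols, total RNA was isolated with an RNeasy kit and paired-end libraries were made with a TruSeq RNA kit.

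The authors deposited whole-number read counts per gene and FPKM values (fragments per kilobase of transcript, scaled to library size) side by side, per the file headers, with a gene identifier, symbol and locus for each gene. Alignment and quantification used HISAT2 and StringTie, per the submitters' processing notes, which name no versions. The genome build, the counting rules and the use of strand are not given in the sources used here. Of the loci in the table, 99.0% equal those of GENCODE release M21 on GRCm38, and 99.6% of the gene identifiers are in that release. The table as used here holds 16383 genes, 29.4% of the 55536 in that release, of which 6440 are protein coding and 6498 have a count of 0 in every library. Totals over this table lie between 4678827 and 5456261 counts, and the library sizes used are the totals over the tested genes, between 4673454 and 5450758. The scale of the FPKM values gave whole-library totals for the 11 libraries whose columns fit together, of which the table holds 29.6% to 31.6%.

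Counts as deposited were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, genes kept by filterByExpr (minimum count 10, minimum total 15), 1 model of all 4 groups and Benjamini-Hochberg adjustment over the 5048 genes tested. An adjusted p under 0.05 is called changed. The contrasts were WT I/R against WT sham, KO I/R against KO sham, KO sham against WT sham, KO I/R against WT I/R, and the interaction of genotype and I/R. Standard errors were computed from the fold change and its F statistic. CPM is the count scaled to library size with TMM factors, in the usual unit of edgeR, given as mean ± SD over 3 libraries. Where every library of a group is at 0, the fold is a lower bound against a floor of 3 counts over the group. The square root of the common dispersion was 0.375.

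On simulated counts for the 5048 genes, the test found 13.1% of the 2-fold and 64.6% of the 4-fold changes for WT I/R against WT sham, and 4.00% and 61.0% for KO I/R against KO sham. For KO sham against WT sham it found 10.1% and 63.9%, for KO I/R against WT I/R 5.10% and 53.6%, and for the interaction 1.03% and 16.0%. Between 1 and 5 unchanged genes were called per contrast. The simulation changed a small part of the genes in a single group and gave all libraries the same spread per gene. The real libraries differed in spread and more genes changed after I/R, so these shares need not hold for the data.

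The gene lists, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. Of 38 lists, 34 had at least 2 tested members. They were tested with camera in limma 3.58.1 (preset correlation 0.01) on the z-scores that edgeR computes from the counts, with Benjamini-Hochberg adjustment over all 170 list tests. Camera with a correlation estimated per list and fry were run beside it, and list scores are means of log2 CPM with a prior count of 2. Named genes are, per contrast, the 12 largest rises and 12 largest falls among changed genes whose groups do not overlap, with at least 5 CPM in a group and a symbol that is not a predicted one. To these the rule adds, from each list, up to 4 changed members, or the 2 of smallest p where none changed, and Lrrk2, Havcr1 and Lcn2 always. Genes printed are part of these, and others are said to be chosen after their values were seen. Reads of near-identical copies may be split by the counting: the values of Hspa1a and Hspa1b, the globins, Acaa1b, Gsta1, Sprr2g, Serpina1f, Acsm2, Slc22a30, Cyp4a14, the ribosomal protein genes and the mitochondrial genes with their nuclear copies are uncertain for that reason, and those of overlapping or antisense genes because strand use is unknown.

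The alternatives tried were RLE and upper-quartile factors, a robust spread, no filter and a stricter filter on low counts (5 CPM in 3 libraries), DESeq2 1.42.0, only the groups of the contrast, the replicate number as a block, a fold threshold (log2 of 1), each library left out in turn, an estimated correlation and fry. Chosen after seeing the data were the use of reads recovered from the FPKM column of KO I/R replicate 2 in place of its counts, the same without KO sham 1, without KO sham 3 or without both, whole-library totals in place of composition factors (with the recovered reads), limma with a trend on log2(FPKM + 1), and limma-voom with weights per library (with the recovered reads). Reads were recovered by multiplying FPKM by the count per FPKM that each gene has in the other libraries. The same steps returned 99.956% of the 6747 deposited counts of KO I/R 1 exactly. With whole-library totals, the median log2 fold change of all genes in WT I/R against WT sham moved from -0.04 to 0.10. No library pair agreed within sampling noise (chi-square per degree of freedom of 26.5 or more within groups), so that every library counts once. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.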

Results

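The study compared the response of the mouse kidney to ischemia and reperfusion (I/R) between wild-type (WT) animals and animals labelled as lacking Lrrk2, which encodes leucine-rich repeat kinase 2. RNA sequencing libraries of 4 groups with 3 libraries each were available: WT sham, WT I/R, KO sham and KO I/R. Total counts over the table ranged from 4678827 (WT sham 3) to 5456261 (WT I/R 3). They were 5205233 and 5225831 in WT I/R 1 and 2, and 5134580, 4713434 and 4801171 in KO I/R 1 to 3. In WT sham 1 and 2 they were 5091230 and 5320861, and in KO sham 1 to 3 they were 5417038, 4965805 and 5194406. The labels do not state that each library came from a separate animal, so the p-values measure only the spread between these samples. Only the genes held in the table could be tested, with 29.6% to 31.6% of the whole-library totals in the 11 libraries whose columns fit together. Other genes may have been measured but are absent here, so each gene list is represented by a part of its members.

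Lrrk2 (ENSMUSG00000036273, chromosome 15, 91673175 to 91816120 in the coordinates of the table) had reads in all 12 libraries. The libraries labelled knockout held 598, 1651 and 207 Lrrk2 counts in sham and 401, 235 and 793 in I/R, against 2053, 1284 and 1839 in WT sham and 320, 381 and 464 in WT I/R. The Lrrk2 level was 351 ± 88.3 CPM in WT sham and 157 ± 142 CPM in KO sham (mean ± SD, n = 3), a log2 difference of -1.16 ± 0.55 (SE) that did not pass the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.809, 95% interval -2.35 to 0.03). After I/R it was 69.6 ± 11.3 CPM in WT and 92.4 ± 47.6 CPM in KO, a log2 difference of 0.41 ± 0.54 (adjusted p = 1). The gene counts therefore did not separate the libraries labelled knockout from WT, and every direction drawn below from the genotype rests on the labels alone. The table has counts per gene and not per exon, so the deleted part of Lrrk2 was not checked. In WT, Lrrk2 fell by 2.33 on the log2 scale after I/R (SE 0.57, edgeR adjusted p = 0.0136), a call lost without WT I/R 1 (0.0643) or WT I/R 2 (0.0545). In the libraries labelled knockout its change after I/R was -0.77 ± 0.54 (adjusted p = 0.323, 95% interval -1.95 to 0.42). With 1 library left out it lay between -1.26 and 0.28, so an absence of change was not shown.

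Several libraries stood apart from their groups. In KO I/R 2, the count column and the FPKM column did not match: 936 genes had an FPKM above 0 and a count of 0, and 533 genes the reverse. Gpx3, a plasma glutathione peroxidase made by the kidney, had 80373 counts there, against 566822 reads recovered from the FPKM column and 405164 and 120389 counts in KO I/R 1 and 3. Across genes the recovered reads correlated with the counts of KO I/R 1 and 3 with r = 0.971 and 0.960. The counts of KO I/R 2 did so with r = 0.925 and 0.915, and with the recovered reads of the same library with r = 0.941, a description across genes, which are not independent replicates. In KO sham 3, mitochondrial genes held 24.7% of the counts, against 5.64% to 10.7% in the other 11 libraries, and Gpx3 held 0.271%. A set of nuclear copies of mitochondrial genes held a further 23.7% there, against 6.51% to 8.93% in the others. Its weight in limma-voom was the lowest (0.136, others 0.642 to 2.85). KO sham 1 held 5 counts on the Y chromosome, against 30 to 157 in the other libraries. It also had 4.03 CPM of Acsm3 and 1.13 CPM of Cyp2j13 and, at the other extreme, 244 CPM of Slc7a12 and 511 CPM of Prlr. Its mean log2 CPM was the highest among sham libraries for tubular injury genes (6.60, others 4.16 to 5.02) and for cytokine and adhesion genes (3.56, others 1.94 to 2.16).

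**Figure D1:**
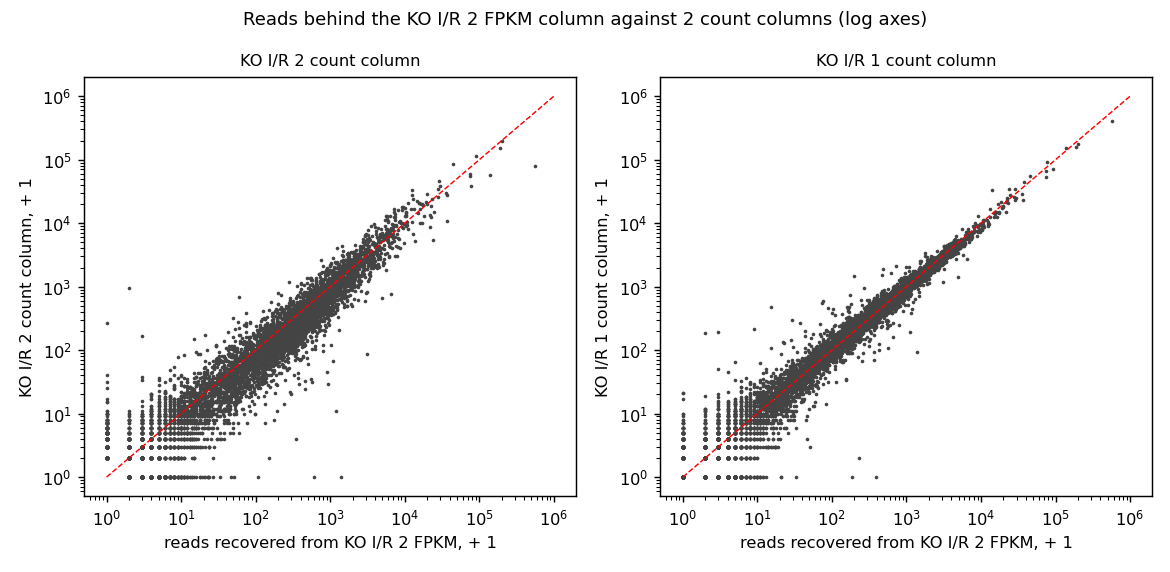
Reads recovered from the FPKM column of KO I/R 2 (horizontal log axis) against the count column of KO I/R 2 (left) and of KO I/R 1 (right), one point per gene. Against its own counts the log2 ratio of KO I/R 2 had an SD of 0.772 over 3540 genes.

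The first comparison asked how the WT kidney changed after I/R. The tubular injury markers Lcn2 (neutrophil gelatinase-associated lipocalin) and Havcr1 (kidney injury molecule 1) rose 418-fold and 370-fold. Lcn2 went from 16.4 ± 5.78 to 6868 ± 922 CPM (log2 8.71 ± 1.14, edgeR adjusted p = 0.000593) and Havcr1 from 11.7 ± 9.01 to 4343 ± 1146 CPM (log2 8.53 ± 1.69, adjusted p = 0.00482; n = 3 per group). Sult1e1, the estrogen sulfotransferase, had no count in WT sham and 28.8 ± 4.43 CPM after I/R, at least 142-fold higher. Slc4a1, the anion exchanger of acid-secreting intercalated cells, fell 34.9-fold (log2 -5.12 ± 0.46, adjusted p = 8.26e-05). Aqp1, the water channel of the proximal tubule and descending limb, fell 10.4-fold (log2 -3.38 ± 0.34, adjusted p = 0.000157), from 3320 ± 482 to 320 ± 86 CPM. In all, 517 genes rose and 540 fell of 5048 tested, and 421 and 470 of these changed at least 2-fold. Without WT sham 3 the log2 change of Havcr1 was 9.35. The split of higher and lower calls differed between settings: with whole-library totals 871 rose and 468 fell, and with limma on FPKM, which differs in more than the scaling, 863 rose and 350 fell. The count of 1057 went to 527 without WT I/R 1, 551 without WT I/R 2, 651 without WT I/R 3, 651 without WT sham 1 and 641 without WT sham 3. A fit of the WT libraries alone called 1995 genes.

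**Figure D2:**
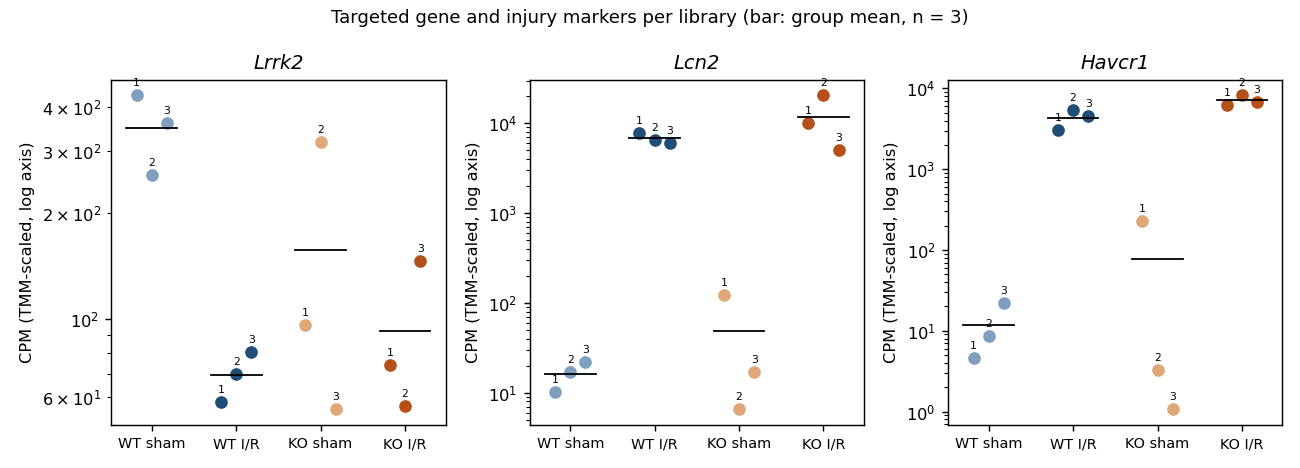
CPM (log axis) of Lrrk2, Lcn2 and Havcr1 in the 12 libraries, one point per library with the group mean as a bar. Lcn2 and Havcr1 lie above sham in every I/R library of the same genotype, and the Lrrk2 points of the libraries labelled knockout overlap those of WT.

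Several lists of injury and inflammation lay higher after I/R in WT. All 6 tested tubular injury genes rose (camera adjusted p = 1.44e-10, adjusted p = 0.152 with an estimated correlation), among them Sox9, a transcription factor of regenerating tubule cells (log2 4.79 ± 0.45), and Gdf15, a stress-induced cytokine (log2 4.15 ± 0.71). Of 7 genes for cytokines and adhesion 6 rose and 1 did not pass (camera adjusted p = 1.18e-05, adjusted p = 0.202 with an estimated correlation). They included the neutrophil chemokine Cxcl2 (log2 7.30 ± 1.25), the interleukin-1 receptor antagonist Il1rn (log2 5.48 ± 1.08) and Socs3, a feedback inhibitor of cytokine signalling (log2 4.09 ± 0.82). Both tested neutrophil genes, Mmp8 and Csf3r, rose (log2 5.63 ± 1.20 and 3.04 ± 0.67). That list's camera adjusted p was 0.0324 (adjusted p = 0.399 with an estimated correlation), and 0.0643 without WT sham 1 and 0.0558 with the reads recovered for KO I/R 2. All 3 tested complement and coagulation genes rose (camera adjusted p = 0.00406, adjusted p = 0.338 with an estimated correlation): the fibrinogen chains Fgb (log2 5.49 ± 1.01) and Fgg (log2 4.47 ± 0.93) and tissue factor F3 (log2 1.87 ± 0.37). All 6 tested genes for extracellular matrix and fibroblasts rose (camera adjusted p = 1.15e-05, adjusted p = 0.158 with an estimated correlation), including the matrix glycoprotein Tnc (log2 3.81 ± 0.52), the collagen Col1a1 (77.4 ± 20.3 to 309 ± 66.3 CPM) and Tgfb1 (log2 1.75 ± 0.28). Adjusted over the list alone, each of these counts was the same. Fold changes from low sham levels moved with single libraries: the log2 value was 6.47 for Fgb, 5.36 for Fgg and 4.70 for Socs3 without WT sham 1, 8.19 for Il1rn, 7.55 for Mmp8 and 4.21 for Csf3r without WT sham 2, 9.21 for Cxcl2 without WT sham 3, and 4.88 for Mmp8 without WT I/R 1.

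Several lists of nephron segments and metabolism lay lower after I/R in WT. Of 8 proximal tubule genes 6 fell and 2 did not pass (camera adjusted p = 6.38e-05, adjusted p = 0.338 with an estimated correlation), among them Aqp1, the organic anion transporter family member Slc22a30 (log2 -3.80 ± 0.75) and Gatm, which makes the creatine precursor guanidinoacetate (log2 -3.01 ± 0.69). Of 5 genes of the loop of Henle and distal tubule 2 fell, Ppp1r1b (log2 -2.98 ± 0.42) and the sodium-calcium exchanger Slc8a1 (log2 -2.66 ± 0.35), and 3 adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.338 with an estimated correlation). Of 7 collecting duct genes 3 fell, led by Slc4a1, and 3 adjusted over the list alone (camera adjusted p = 0.0215, adjusted p = 0.557 with an estimated correlation, and 0.0676 without WT sham 2). All 4 genes for gluconeogenesis and amino acid metabolism fell (camera adjusted p = 0.0102, adjusted p = 0.456 with an estimated correlation), including glucose-6-phosphatase G6pc (log2 -4.76 ± 0.77). Of 5 genes for steroid and cholesterol synthesis 3 fell, 3 also adjusted over the list alone (camera adjusted p = 0.00870, adjusted p = 0.399 with an estimated correlation). They included the sterol demethylase Cyp51 (log2 -3.72 ± 0.31) and the isomerase Idi1 (log2 -3.11 ± 0.64). Without WT sham 1 the log2 change was -3.35 for G6pc and -2.30 for Gatm. The acyl-CoA dehydrogenase Acadm, an enzyme of fatty acid oxidation, fell by 2.69 on the log2 scale (SE 0.36), with 6 other members of its list not past the test (camera adjusted p = 0.0782).

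The remaining lists did not pass camera in WT. Members moved in both directions among 6 monocyte and macrophage genes (camera adjusted p = 0.805): the integrin Itgam rose (log2 2.99 ± 0.57), the growth factor receptor Csf1r fell (log2 -1.65 ± 0.31), and the chemokine receptor Cx3cr1 fell (log2 -2.58 ± 0.61), a call lost without WT I/R 1 (0.0577), without WT I/R 3 (0.0526) and with whole-library totals (0.0514). Among 4 heat shock genes 3 rose (camera adjusted p = 0.0860), including Hspa1a (log2 2.90 ± 0.58, and 1.81 without WT I/R 1). Of 4 immediate early genes 1 rose, Btg2 (log2 2.15 ± 0.50; camera adjusted p = 0.0859). Of 4 genes of the unfolded protein and integrated stress response, 1 rose, Trib3 (log2 3.84 ± 0.53), and 1 fell, Herpud1 (log2 -1.53 ± 0.41; list 0.598). The Herpud1 call was lost without WT sham 1 (0.0930), WT I/R 1 (0.0753), WT I/R 2 (0.0767) or WT I/R 3 (0.0752). Gsta1 of the NRF2 and redox list rose (log2 3.98 ± 0.66, 1 of 4 genes; list 0.888). Gadd45a of the p53 targets (log2 1.86 ± 0.29, 1 of 3 genes; list 0.441) and Birc3 of regulated cell death (log2 1.23 ± 0.28, 1 of 5 genes; list 0.537) rose too. Of 10 lysosome and autophagy genes 2 rose, including Gpnmb (log2 3.94 ± 0.83, and 4.63 without WT sham 1), and 1 fell (list 0.766). No member passed among 9 cell cycle genes (camera adjusted p = 0.601), 6 circadian genes (0.639), 4 interferon genes (0.735), 3 podocyte genes (0.978), 3 endothelial genes (0.525), 3 red blood cell genes (0.652) or 5 neighbours of Lrrk2 (0.518), nor in the pairs of adipocyte (0.735) and mitochondrially encoded genes (0.502). The other lists were those for lymphocytes (0.405), oxidative phosphorylation (0.0774), glycolysis and hypoxia (0.598), LRRK2 partners (0.894), ribosomal proteins (0.0859) and sex-biased kidney genes (0.0570). Lists for antigen presentation and the adrenal gland had 1 tested gene each, and those for sex chromosome genes and skeletal muscle had 0.

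The second comparison asked how the kidneys labelled knockout changed after I/R. Lcn2 rose 241-fold, from 49.2 ± 65.1 to 11905 ± 7875 CPM (log2 7.91 ± 1.10, edgeR adjusted p = 0.000863). The fibrinogen chain Fgb rose 120-fold, from 7.28 ± 10.7 to 907 ± 213 CPM (log2 6.90 ± 1.05, adjusted p = 0.00141), and Sult1e1 was at least 326-fold higher, from no count to 64.8 ± 31.3 CPM. Uroc1, an enzyme of histidine breakdown, fell by 4.95 on the log2 scale (SE 0.27, adjusted p = 1.61e-06), from 173 ± 33.5 to 5.55 ± 0.662 CPM, and the proximal tubule phosphate transporter Slc34a3 fell 19.5-fold (log2 -4.29 ± 0.46, adjusted p = 0.000174). Havcr1 rose 90.4-fold (log2 6.50 ± 1.54, adjusted p = 0.0108), a call lost in a fit of these 6 libraries alone (0.0682). These folds rested on KO sham 1: without it the rise was 3100-fold for Havcr1, 1024-fold for Lcn2 and 800-fold for Fgb, so their sizes are not compared with those in WT. KO I/R 2 moved Lcn2 as well, to a log2 change of 7.27 without that library and 7.32 with its recovered reads, with which Slc34a3 was at -3.56. In all, 603 genes rose and 582 fell of 5048, and 485 and 509 of these changed at least 2-fold. With limma on FPKM 793 rose and 335 fell. The fit of these 6 libraries alone called 364 genes.

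All 6 tubular injury genes rose in the kidneys labelled knockout (camera adjusted p = 2.21e-10, adjusted p = 0.152 with an estimated correlation), including Sox9 (log2 4.29 ± 0.43, and 4.95 without KO sham 1) and the chaperone clusterin, Clu (log2 3.89 ± 0.38). All 3 complement and coagulation genes rose (camera adjusted p = 0.000881, adjusted p = 0.152 with an estimated correlation). Of 7 cytokine and adhesion genes 5 rose, and 6 adjusted over the list alone (camera adjusted p = 0.00911, adjusted p = 0.348 with an estimated correlation). All 4 ribosomal protein genes rose (camera adjusted p = 0.00406, adjusted p = 0.476 with an estimated correlation), Rplp0 most (log2 2.09 ± 0.41), and each of these 4 calls was lost in the fit of these 6 libraries alone. KO I/R 2 moved this group: the log2 change of Rplp0 was 1.40 without that library and 1.57 with its recovered reads. Of 8 proximal tubule genes 4 fell, 4 also adjusted over the list alone (camera adjusted p = 0.000397, adjusted p = 0.348 with an estimated correlation), including Gatm (log2 -4.22 ± 0.73, and -3.48 without KO sham 1) and Aqp1 (log2 -2.51 ± 0.33). G6pc (log2 -3.67 ± 0.73) and Cyp51 (log2 -2.97 ± 0.30) fell, while Acaa1b, a peroxisomal thiolase of fatty acid oxidation, rose (log2 1.74 ± 0.31). The lists that hold these genes did not pass camera in this comparison. Fdps, of the same sterol list as Cyp51, went the other way (log2 1.89, and 1.24 without KO I/R 2). The extracellular matrix list did not pass (3 of 6 genes rose, camera adjusted p = 0.220).

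Further lists passed camera in the kidneys labelled knockout but rested on single libraries. Of 4 lymphocyte genes 3 fell, and 4 adjusted over the list alone (camera adjusted p = 0.0237, adjusted p = 0.348 with an estimated correlation), among them the T cell coreceptor Cd8a (log2 -3.96 ± 0.82, and -3.34 without KO sham 3, -3.35 without KO I/R 1 and -4.76 without KO I/R 2). This p was 0.0593 without KO sham 1, 0.0509 without KO sham 3 and 0.0815 without KO I/R 3. Of 7 collecting duct genes 2 fell, including Slc4a1 (log2 -4.09 ± 0.44), and 3 adjusted over the list alone (camera adjusted p = 0.0345, adjusted p = 0.605 with an estimated correlation). It was 0.157 without KO sham 3 and 0.0815 without KO I/R 3. In the loop of Henle and distal tubule 2 of 5 genes fell, Ppp1r1b (log2 -2.86 ± 0.42) and Slc8a1 (log2 -2.69 ± 0.35), and 2 adjusted over the list alone. That list lay just under the threshold (camera adjusted p = 0.049996, adjusted p = 0.414 with an estimated correlation), at 0.0901 without KO sham 1, 0.171 without KO I/R 3 and 0.0939 with whole-library totals.

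Fold changes after I/R were compared between WT and the kidneys labelled knockout, which share no library. Across 5048 genes Pearson's r was 0.814 and Spearman's rho 0.794, a description across genes, which are not independent replicates. With no filter on low counts r was 0.404. Both groups had 357 genes that rose, against 61.8 for independent lists of these sizes, and 346 that fell, against 62.3. Opposite calls were made for 2 genes. Calls in WT alone numbered 352 and in KO alone 480, but a call in one group and not in the other is no test of a difference, and the interaction below is that test. Of 1537 genes called in either, 96.9% had the same sign in both.

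**Figure D3:**
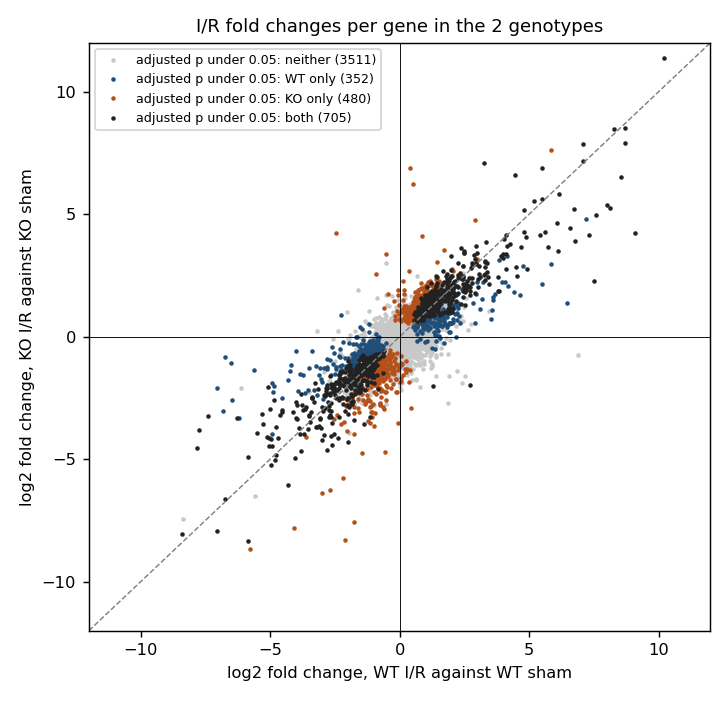
Log2 fold change after I/R in WT (horizontal axis) against that in the kidneys labelled knockout (vertical axis), one point per gene tested, coloured by where edgeR called the gene. Pearson's r across the 5048 genes was 0.814.

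The third comparison set sham kidneys labelled knockout against WT sham kidneys. The thiolase Acaa1b was 2.56-fold lower, at 1487 ± 250 against 3804 ± 1081 CPM (log2 -1.35 ± 0.30), and the mitochondrial dehydrogenase Acadl 1.53-fold lower (log2 -0.61 ± 0.20). The cholesterol synthesis enzyme Sqle was 2.65-fold lower (log2 -1.41 ± 0.40; n = 3 per group). None of these passed the test over all genes (edgeR adjusted p = 0.269 for Acaa1b, 0.706 for Acadl and 0.586 for Sqle), while DESeq2 called Acaa1b (0.00340) and Acadl (0.0393). As lists, fatty acid oxidation and peroxisome (7 genes, camera adjusted p = 1.15e-05, adjusted p = 0.189 with an estimated correlation) and steroid and cholesterol synthesis (5 genes, camera adjusted p = 3.11e-07, adjusted p = 0.152 with an estimated correlation) lay lower. Adjusted over the list alone, 3 and 4 of their genes passed, all lower, against 0 over all genes. Both lists stayed past the threshold when any 1 library was left out, and fry gave 0.0342 and 0.0366. KO sham 3, the library with 24.7% mitochondrial counts, had the lowest KO sham score in both lists (7.76 against 8.79 and 9.60, and 5.53 against 6.16 and 6.69), and KO sham 1 (9.60) lay within the WT sham range (9.53 to 10.33) for fatty acid oxidation. The edgeR test called 0 of 5048 genes. An unadjusted p under 0.05 was found for 285, close to the share of 0.05 that unchanged genes alone would give. That number was 193 without WT sham 2 and 570 without KO sham 2, the extremes with 1 library left out. With the reads recovered for KO I/R 2 it was 445, so the closeness to that share depended on the libraries used. DESeq2 called 28, limma on FPKM 4 and limma-voom 1. Without WT sham 1 edgeR called 2 genes, Gm42031 and Igkc, and without KO sham 1 also 2, Cyp4a14 and Ugt1a6a, all 4 chosen after their values were seen.

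Other lists that passed camera between the sham groups rested on single libraries. The extracellular matrix list lay higher (camera adjusted p = 0.00406, adjusted p = 0.348 with an estimated correlation), with 3 of its 6 genes past the test adjusted over the list alone and 0 over all genes. Pdgfrb, a receptor of pericytes and fibroblasts, differed by a log2 of 0.92 ± 0.25, and without KO sham 1 the list's p was 0.0901. The cytokine and adhesion list lay higher (camera adjusted p = 0.0270, adjusted p = 0.459 with an estimated correlation), but at 0.823 without KO sham 1 and 0.0975 without WT sham 1. Gluconeogenesis and amino acid metabolism lay lower (camera adjusted p = 0.0114, adjusted p = 0.456 with an estimated correlation), at 0.142 without KO sham 1, 0.247 without WT sham 1 and 0.0503 without KO sham 3. Cell cycle genes lay lower (camera adjusted p = 0.0132, adjusted p = 0.523 with an estimated correlation), at 0.403 without KO sham 2 and 0.203 without WT sham 2. Red blood cell genes lay higher (camera adjusted p = 0.0331, adjusted p = 0.557 with an estimated correlation), but the p was 0.111 without WT sham 2, 0.247 without WT sham 3, 0.179 without KO sham 2 and 0.317 without KO sham 3. In these 4 lists 0 genes passed over all genes or adjusted over the list alone. Havcr1 and Lcn2 differed by log2 2.74 ± 1.32 and 1.59 ± 0.85, and by -2.36 and -0.50 without KO sham 1. Of 74 tested genes within 10 Mb of Lrrk2, 0 were called, and 4 had an unadjusted p under 0.05 against 281 of the 4973 others (Fisher's exact test p = 1).

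**Figure D4:**
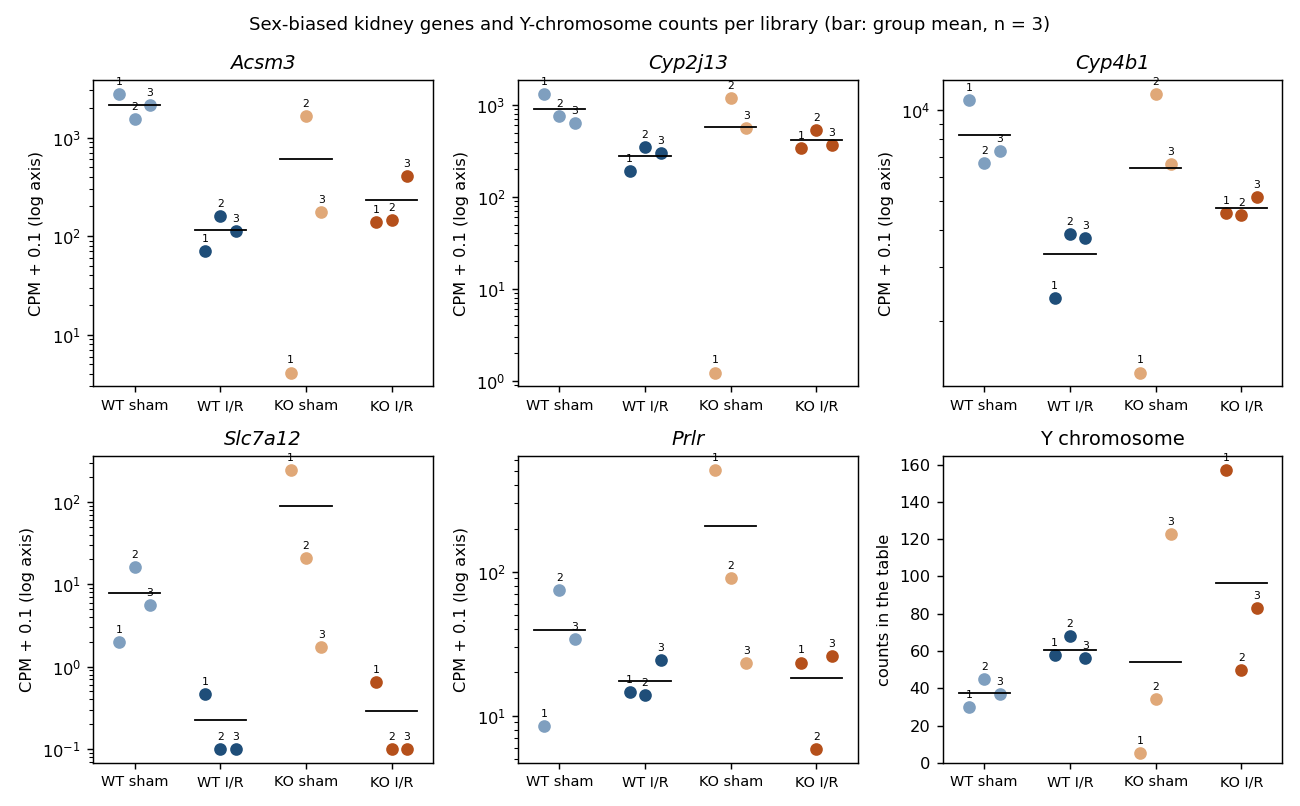
CPM (log axis) of Acsm3, Cyp2j13, Cyp4b1, Slc7a12 and Prlr, and counts on the Y chromosome, one point per library with the group mean as a bar. KO sham 1 lies apart from the other sham libraries in Acsm3, Cyp2j13, Cyp4b1, Slc7a12, Prlr and the Y chromosome counts.

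The fourth comparison set I/R kidneys labelled knockout against WT I/R kidneys. The collagen genes Col5a1 and Col1a1 were 2.22-fold and 2.01-fold lower (log2 -1.15 ± 0.32 and -1.01 ± 0.35), Col1a1 at 154 ± 70.2 against 309 ± 66.3 CPM. The mitotic regulator Cdc20 was 2.75-fold lower (log2 -1.46 ± 0.40), and the fibrinogen chain Fgb 5.34-fold higher (log2 2.42 ± 0.84), at 907 ± 213 against 170 ± 18.5 CPM (n = 3 per group). For each of them the edgeR adjusted p was 1. The extracellular matrix list lay lower (6 genes, camera adjusted p = 2.93e-06, adjusted p = 0.152 with an estimated correlation), and 3 of its genes passed adjusted over the list alone, all lower, against 0 over all genes. Cell cycle genes lay lower as well (9 genes, camera adjusted p = 0.00138, adjusted p = 0.399 with an estimated correlation), with 1 lower adjusted over the list alone. Both lists stayed past the threshold when any 1 library was left out, while fry gave 0.0649 and 0.220. The edgeR test called 0 of 5048 genes. An unadjusted p under 0.05 was found for 140, below the share of 0.05 that unchanged genes alone would give. That number was 90 without WT I/R 1 and 195 with the reads recovered for KO I/R 2. It was 338 with those reads and without KO sham 3, and 689 with limma-voom. The share thus depended on the libraries and the method, and a low one does not show an absence of differences. DESeq2 called Kcnj16 and Rreb1, limma on FPKM called Mir7118, and limma-voom called Fgb, Col1a1, Col6a2, Plpp2 and Col5a1. Rreb1, Mir7118, Col6a2 and Plpp2 were chosen after their values were seen. Without WT I/R 1 edgeR called 1 gene, the pseudogene Rps2-ps10, also chosen after its values were seen.

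Fatty acid oxidation and peroxisome genes lay higher in I/R kidneys labelled knockout than in WT I/R (camera adjusted p = 0.00327, adjusted p = 0.348 with an estimated correlation), but the p was 0.0764 without KO I/R 3. Acaa1b differed by a log2 of 0.81 ± 0.30. Complement and coagulation genes lay higher (camera adjusted p = 0.0238, adjusted p = 0.348 with an estimated correlation), with 2 of 3 past the test adjusted over the list alone, Fgb and Fgg (log2 2.05 ± 0.84 for Fgg). That p was 0.0763 without WT I/R 2, 0.0535 without WT I/R 3, 0.0806 without KO I/R 1 and 0.105 without KO I/R 3. Heat shock genes lay lower (camera adjusted p = 0.0134, adjusted p = 0.436 with an estimated correlation), and this rested on KO I/R 2, whose columns disagree: the p was 0.419 without that library and 0.963 with its recovered reads. It was also 0.226 without WT I/R 1 and 0.0864 without KO I/R 3. Endothelial genes lay just past the threshold (lower, camera adjusted p = 0.049996, adjusted p = 0.414 with an estimated correlation). Their p was 0.101 without WT I/R 2, 0.144 without WT I/R 3, 0.0708 without KO I/R 2, 0.518 without KO I/R 3 and 0.0589 with RLE factors. Kcnj16, a potassium channel subunit of the distal tubule, had a small p within its list and was 12.1-fold higher in KO I/R (edgeR adjusted p = 1; 600, 649 and 48.7 CPM in its 3 libraries). Its level was 432 ± 333 CPM in KO I/R and 35.6 ± 7.30 CPM in WT I/R. Near Lrrk2, 0 of 74 genes were called, and 1 had an unadjusted p under 0.05 against 139 of 4973 others (Fisher's exact test p = 0.724). Limma on FPKM called 1 gene there, Mir7118.

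The last comparison asked whether the change after I/R differed between WT and the kidneys labelled knockout. Acaa1b went from 1487 ± 250 to 4969 ± 1062 CPM after I/R in KO and from 3804 ± 1081 to 2826 ± 515 CPM in WT, a difference between the changes of log2 2.17 ± 0.42. For the platelet-derived growth factor receptor Pdgfrb the change was lower in KO than in WT by a log2 difference of -1.56 ± 0.35, and for Col5a1 by -1.97 ± 0.45. The edgeR adjusted p of these differences was 0.260, 0.442 and 0.442, while DESeq2 called all 3 (0.000214, 0.0382 and 0.0320). As a list, fatty acid oxidation and peroxisome genes had a higher change in KO (7 genes, camera adjusted p = 1.93e-07, adjusted p = 0.152 with an estimated correlation). The mean log2 CPM of this list in KO differed from that in WT by -1.12 in sham and by 0.57 after I/R. The larger part of its interaction thus lay between the sham groups. The change of the extracellular matrix list was lower in KO (6 genes, camera adjusted p = 3.11e-07, adjusted p = 0.152 with an estimated correlation). Adjusted over the list alone, 3 genes of each passed, against 0 over all genes, and fry gave 0.0244 for both. Both stayed past the threshold when any 1 library was left out. Of the KO sham libraries, KO sham 3, with 24.7% mitochondrial counts, had the lowest fatty acid oxidation score (7.76 against 8.79 and 9.60). The edgeR test called 0 of 5048 genes. An unadjusted p under 0.05 was found for 265, close to the share of 0.05 that unchanged genes alone would give. That number was 163 without WT I/R 1 and 424 without KO sham 2, the extremes with 1 library left out. With the reads recovered for KO I/R 2 it was 338, so this closeness depended on the libraries too. DESeq2 called 16, limma on FPKM 0 and limma-voom 0. Without KO sham 1 edgeR called Cyp4a14 and Ugt1a6a, without WT sham 1 Gm42031 and without WT I/R 1 Rps2-ps10, all chosen after their values were seen.

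Steroid and cholesterol synthesis also had a higher change in KO than in WT (5 genes, camera adjusted p = 6.38e-05, adjusted p = 0.255 with an estimated correlation), with the farnesyl diphosphate synthase Fdps at a log2 difference of 1.97 ± 0.65. This list stayed past the threshold when any 1 library was left out, but fry gave 0.0909, and reads recovered for KO I/R 2 without KO sham 1 and 3 gave 0.0517. The list's mean log2 CPM was alike in KO I/R and WT I/R (5.97 and 5.94) and lower in KO sham than in WT sham (6.13 and 7.56). The interaction of this list thus restates the difference between the sham groups. Cytokine and adhesion genes had a lower change (7 genes, camera adjusted p = 0.00327, adjusted p = 0.348 with an estimated correlation), at 0.355 without KO sham 1. Gluconeogenesis and amino acid metabolism had a higher change (4 genes, camera adjusted p = 0.0114, adjusted p = 0.456 with an estimated correlation), at 0.123 without WT sham 1, 0.0539 without KO sham 1 and 0.0609 without KO I/R 3. Its mean log2 CPM in KO differed from that in WT by -1.49 in sham and by 0.39 after I/R. Most of this interaction thus lay between the sham groups. Lymphocyte genes had a lower change (4 genes, camera adjusted p = 0.0295, adjusted p = 0.348 with an estimated correlation). Their p was 0.0860 without KO sham 1, 0.0716 without KO sham 3, 0.0946 without KO I/R 3, 0.0628 without KO I/R 2, 0.0761 without WT sham 3, 0.0720 without WT I/R 1 and 0.0538 without WT I/R 2. In these 4 lists 0 genes passed over all genes or adjusted over the list alone.

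**Figure D5:**
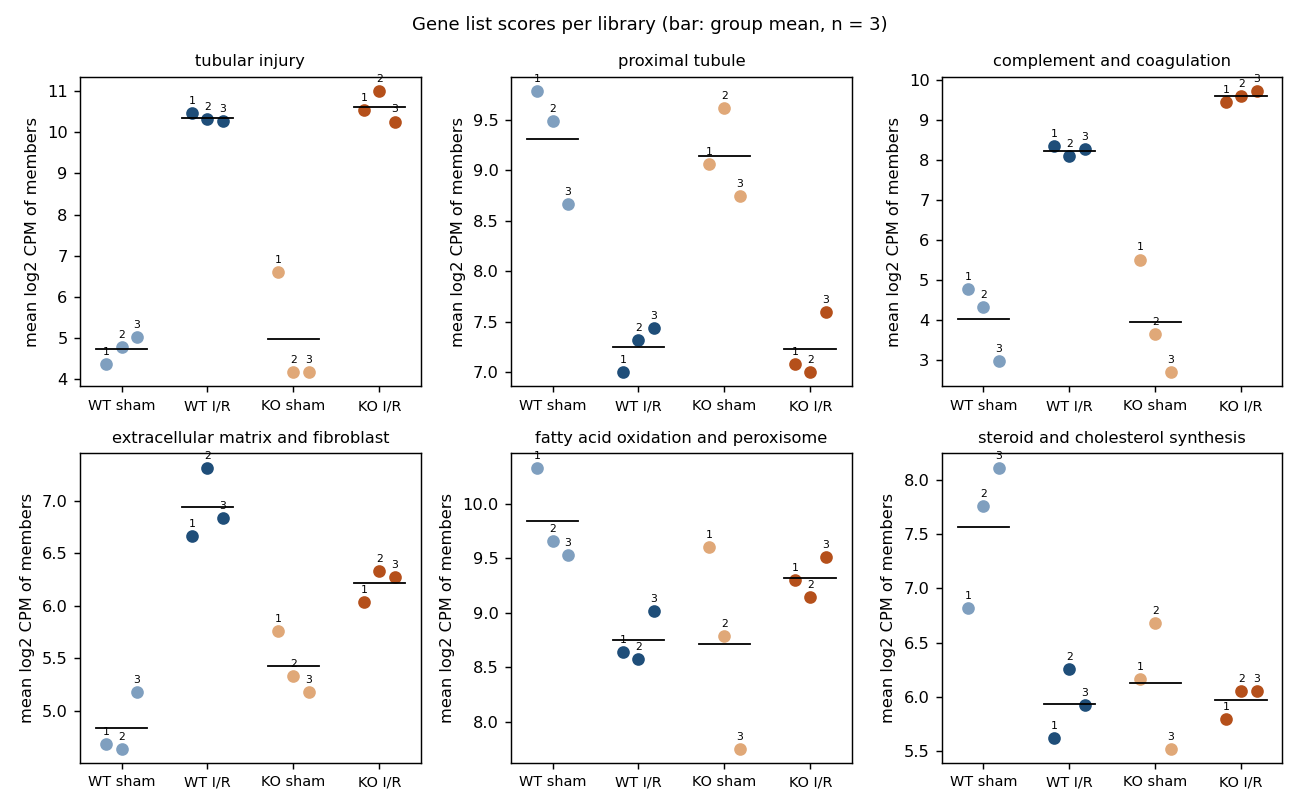
Mean log2 CPM of the members of selected gene lists in each of the 12 libraries, one point per library and the group mean as a bar. With 3 libraries per group an exact permutation test between groups cannot give a p below 0.1.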

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

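All tests on single libraries and on Lrrk2 in this part were chosen only after the result was seen. In KO I/R 2, 936 genes had an FPKM above 0 beside a count of 0, a signal in values that the comparisons did not use. The change after I/R differed between WT and the libraries labelled knockout, by camera on the interaction, for 6 gene lists. They were fatty acid oxidation and peroxisome (adjusted p = 1.93e-07), extracellular matrix and fibroblast (3.11e-07), steroid and cholesterol synthesis (6.38e-05), cytokines and adhesion (0.00327), gluconeogenesis and amino acid metabolism (0.0114) and lymphocyte genes (0.0295). None of the 6 passed with an estimated correlation (smallest adjusted p = 0.152), and 2 passed with fry. The cytokine, gluconeogenesis and lymphocyte lists each lost their camera call when certain single libraries were left out. For steroid and cholesterol synthesis the interaction restates the difference between the sham groups.

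The columns of KO I/R 2 disagreed. Set on the gene lengths of the other libraries, 100% of its 5788 FPKM values under 1000 reads were whole reads within 0.05 reads. The FPKM column thus rested on whole read counts, which the same reads counted in another way would give too. The columns may come from different libraries. Against another scale or gene length as the whole source, 936 genes had a count of 0 at an FPKM above 0. The log2 ratio of the columns correlated with log2 exon length (r = -0.344 over 3540 genes), so a part tied to length stays open. Against 1 set of reads counted in 2 ways, the SD of the log2 ratio was 0.808 over 234 genes with 1 transcript that overlap no other gene. For pairs of different I/R libraries of a group without this count column, that SD was 0.296 to 0.532. The count column lay further from KO I/R 1 and 3 (0.937 and 1.03) than from its own FPKM column, so that a link between the columns, such as reads shared in part, stays open. This closeness does not show a link: in log2 CPM the count column correlated with WT I/R 2 as with its own recovered reads (r = 0.945 each). Which column belongs to the labelled sample stays open too, and no biological explanation was tested.

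KO sham 1 stood apart in sex-biased kidney genes. It held 5 counts on the Y chromosome against 30 to 157 in the other libraries, so it may come from an animal of the other sex. Slc7a12 and Prlr lay above the mean of the other sham libraries by a log2 of at least 3.89, at 244 and 511 CPM. Against tubular injury as the source, they were at most 0.56 and 25.9 CPM in the I/R libraries. Their log2 change after I/R in WT was -5.77 and -1.16, but Slc7a12 was at 16.0 CPM or less in WT sham. Prlr overlapped between WT sham (8.43 to 74.5 CPM) and WT I/R (13.7 to 24.2 CPM). Slc22a12 of the same list did not stand apart (38.2 CPM, other sham libraries 24.4 to 120). Its tubular injury score was 6.60, the highest among sham libraries but below the 10.26 or more of the I/R libraries, while its Acsm3, Cyp2j13 and Cyp4b1 lay below every I/R library by a log2 of at least 0.82, which argues against injury as their source too. A wrong sample in this place stays open as well, and sex is not given in the labels.

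Lrrk2 had reads in every library labelled knockout. The lowest count was 207, which argues against a whole transcript missing from these libraries. A deletion that leaves most of the transcript could give such counts and cannot be told apart from an intact gene, because the table holds counts per gene and the KO I/R mean was 1.33 times that of WT I/R. A swap between the sham groups cannot be told apart either: the lowest WT sham level was 257 CPM, but a knockout library need not be low.

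Other splits of the same libraries were counted for each comparison. For WT I/R against WT sham the real split called 1057 genes and the highest other 1, so that 1 of 10 splits called as many. For KO I/R against KO sham the values were 1185 and 1, again 1 of 10. In both comparisons every other split mixes I/R and sham libraries within each group. The large change after I/R then enters the spread within groups. Few calls were bound to follow, so the gap between the real and the other splits is no test of chance. For KO sham against WT sham the real split called 0 and the highest other 2, and for KO I/R against WT I/R 0 and 1, with edgeR (unadjusted p under 0.05: 285 and 140 genes; DESeq2 28 and 2; limma on FPKM 4 and 1; limma-voom 1 and 5). The 10 splits of 6 libraries are too few for a share under 0.05. For the interaction edgeR called 0 genes in the real split (265 at an unadjusted p under 0.05; DESeq2 16, limma on FPKM 0, limma-voom 0), and the highest of the 100 splits drawn gave 3. Where the real split called 0 genes, every split gives at least as many (10 of 10 and 100 of 100), which says nothing about chance.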

How the results depend on the processing

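Settings that add reads from FPKM for KO I/R 2, whole-library totals, limma on FPKM and limma-voom were chosen only after the results were seen. Pseudocount alternatives were not run, since genes and lists were tested on counts, and the interaction has no fit of its own groups alone. For each value that moved, its cause was not tested. The count of genes changed in WT I/R against WT sham, 1057, was 1995 with only the groups of the contrast, 2177 with limma-voom and 527 to 748 with 1 library left out. With KO I/R 2 reads from FPKM it was 2141 without KO sham 3, 1609 without KO sham 1 and 2182 without both. For KO I/R against KO sham, 1185 became 364 with only the groups, 1898 with limma-voom, 1818 with reads from FPKM and without KO sham 3, and 834 to 1367 with 1 library left out. For KO sham against WT sham edgeR called 0 (285 at an unadjusted p under 0.05), against 5 with no filter, 28 with DESeq2, 4 with limma on FPKM, 1 with limma-voom and 0 to 2 with 1 library left out. With reads from FPKM it was 8 without KO sham 1 and 4 without KO sham 1 and 3, where the lone KO sham library is assumed to vary like the other groups. For KO I/R against WT I/R edgeR called 0 (140 unadjusted), against 2 with DESeq2, 1 with limma on FPKM (1 gene near Lrrk2 among these), 5 with limma-voom and 0 to 1 with 1 library left out. For the interaction edgeR called 0 (265 unadjusted), against 3 with no filter, 16 with DESeq2, 4 and 5 with reads from FPKM without KO sham 1 and without both, and 0 to 2 with 1 library left out.

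The correlation of the I/R fold changes, 0.814, was 0.404 with no filter, 0.851 with the stricter filter, 0.837 with only the groups, 0.774 and 0.773 with reads from FPKM without KO sham 1 and without both, and 0.748 to 0.812 with 1 library left out. Lists past camera numbered 10 in WT I/R against WT sham (17 with no filter, 9 to 13 with 1 library left out), 8 in KO I/R against KO sham (5 to 8), 7 in KO sham against WT sham (4 with reads from FPKM without KO sham 1, 2 with fry, 4 to 7), 6 in KO I/R against WT I/R (0 with fry, 5 to 5) and 6 in the interaction (2 with fry, 5 to 8). With an estimated correlation it was 0 in each. Lrrk2 turned sign with 1 library left out in KO I/R against KO sham (-1.26 to 0.28) and KO I/R against WT I/R (-0.0931 to 0.66). Between the sham groups Lcn2 ranged from -0.50 to 2.11 and Havcr1 from -2.36 to 3.56 with 1 library left out. With reads from FPKM they were -0.51 and -2.35 without KO sham 1, and -1.32 and -1.83 without both. In the interaction Lcn2 ranged from -1.44 to 1.29 and Havcr1 from -2.85 to 3.07, and with reads from FPKM they were 0.71 and 2.85 without KO sham 1 and 1.51 and 2.32 without both. With limma-voom Lcn2 was at 0.0032. The heat shock list in KO I/R against WT I/R turned direction with reads from FPKM at an adjusted p of 0.997 without KO sham 3 and 0.994 without KO sham 1 and 3, against 0.963 with those reads alone. Of 151 calls of named genes, 151 held with RLE, upper-quartile and robust settings, 150 with DESeq2, 149 with reads from FPKM, 143 with no filter and 142 with whole-library totals. With only the groups 113 of 144 held, with limma on FPKM 119 of 128, without WT I/R 1 56 of 77 and without KO sham 2 57 of 74, the fewest in WT and KO with 1 library left out. Of 37 list calls, 36 held with RLE, 35 with reads from FPKM and 22 with fry.

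The numbers 1 to 3 were also fitted as a replicate block. It gave 1031 and 1134 changed genes after I/R in WT and KO and 0 in each genotype comparison, ended 12 of 151 calls of named genes, and moved 3 list calls over 0.05: the loop of Henle in KO (0.0521), red blood cells (0.0568) and endothelium (0.0513). Residuals of libraries with the same number correlated at a median of 0.052 (-0.370 to 0.299).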

Other observations

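The tests in this part were planned, and Cyp4a14, Ugt1a6a and Idi1 between the sham groups were picked only after their values were seen. Cyp4a14, a fatty acid hydroxylase, and Ugt1a6a, a glucuronosyltransferase, were called between the sham groups by edgeR when KO sham 1 was left out (log2 -4.69, adjusted p = 0.0172, and 3.74, adjusted p = 0.00699). Aurkb, a mitotic kinase, rose after I/R in the kidneys labelled knockout (log2 2.20 ± 0.42, adjusted p = 0.00421), within a cell cycle list in which 3 of 9 genes rose and 1 fell. Of the sterol genes, Idi1 was at 247 ± 84.3 CPM in WT sham and 79.5 ± 69.4 CPM in KO sham. In WT after I/R it was at 28.6 ± 15.7 CPM, and in KO at 27.3 ± 10.3 CPM.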
